A study of Mus musculus with 6 samples.

How the data were processed

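RNA from 6 samples of mouse C2C12 myoblasts was profiled on Affymetrix Mouse430_2 arrays, 1 array per sample, 3 for untreated cells and 3 for cells given sodium pyruvate. Per the labels' protocols, total RNA was extracted with TRIzol and transcribed in vitro into biotin-labelled cRNA with a commercial T7 kit. The deposited values are MAS5 signals, per the submitters' processing notes, in units of intensity on a linear scale, 1 per probe set and array. MAS5 condenses the perfect-match and mismatch probes of a probe set into 1 signal and can return values near 0. Its version and settings are not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets was 150.0 on each of the 6 arrays, so the authors had scaled every array to a common trimmed mean. That scaling was kept. It fixes the overall level of each array, so a change in total RNA per cell cannot be seen in these signals, and it does not align the shapes of the distributions. Scanner images, probe-level files and detection calls were not used here. Arrays carry no read depth, and the number of arrays limits the precision.

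The value table held 45101 probe sets, of which 64 were Affymetrix controls and were left out of the tests. Gene symbols came from the platform annotation, checked through Entrez gene identifiers against a RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only. Of the other 45037 probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none, and no gene was named from a probe set with several. Of those with 1 symbol, 34741 matched through the Entrez identifier and 0 symbols needed updating. A gene was represented by its brightest probe set over all 6 arrays, and the other probe sets of a gene were compared with it.

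Signals were transformed as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. Probe sets entered the test if their mean over all 6 arrays was at or above the median of the non-control probe sets, a log2 value of 5.53 or a signal of about 30.3. This left 22519 probe sets and 10685 genes. Pyruvate was compared with untreated by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided, no blocking factor), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. All adjusted p-values below come from this limma model unless another test is named. The labels do not say whether the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

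Before the data were examined, 40 gene lists were fixed, and 39 of them had a measured member. Of 1048 listed members, 922 matched by current symbol and 19 by synonym, and 107 had no probe set of 1 symbol. Each list was tested against all other genes with limma's camera, at its preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks only whether members move and does not compare them with other genes, were run as alternatives. The genes named were also fixed by a rule. It took the 12 highest and 12 lowest log2 changes among genes past the threshold whose 3 pyruvate values all lay on one side of all 3 untreated values, passing over predicted or clone-named transcripts. It added up to 4 members past the threshold from each list, those with the largest absolute change, or 2 members as values where none passed. It always named Ppargc1a, Ppargc1b, Pprc1, Nrf1, Gabpa, Tfam, Esrra, Cycs, Cox4i1, Cs, Pdk4, Ldha, Ldhb, Slc16a1, Myod1, Myog, Cdkn1a, Slc5a3 and Slc6a6, and Akr1b3, which had no probe set of 1 symbol and is not analysed here. Where the report draws on this rule, the examples are a selection of the genes it took.

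The alternatives were pseudocounts of 1 and 64, no signal filter and a stricter signal filter, quantile normalization, median centring, limma without the variance trend and with robust variances, array weights, the replicate number as a block, the mean over a gene's probe sets, a minimum absolute log2 change of 1, and each array left out in turn. Cyclic loess normalization was added after the data were seen. Control probe sets for spiked-in bacterial and phage transcripts, actin, Gapdh and 18S RNA were read per array, with exact two-sided permutation tests, for which 3 against 3 arrays allow no p below 0.1. Figures were drawn with matplotlib 3.10.9.

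The limma step was tested on simulated data for this comparison, built from the real means and spreads of the arrays, with 22519 probe sets in the fit and known changes added to a few. It recovered 2.08% of 48 probe sets changed by 0.25 on the log2 scale, 42.9% of 49 changed by 0.5, 93.5% of 46 changed by 1 and 100% of 47 changed by 2. A list of 40 further probe sets was shifted by 0.3, of which 7 were called. Of 123 probe sets called in all, 4 carried no simulated change. In the real data 7250 probe sets were called, so the Benjamini-Hochberg adjustment was less strict there than in the simulation. The shares recovered are thus not those of the real comparison, where smaller changes could pass.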

Results

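C2C12 is a line of mouse myoblasts, muscle precursor cells that fuse into myotubes when they differentiate. The cells, undifferentiated by their labels, were seeded in 100 mm dishes and incubated for 72 h, either in basal medium or in medium with 50 mM sodium pyruvate. Both media were DMEM with 10% fetal bovine serum, 4 mM glutamine and 1% antibiotics. There were 3 untreated and 3 pyruvate samples, 1 array each. By its title the study asked whether pyruvate drives mitochondrial biogenesis without the coactivator PGC-1alpha, so the comparison of pyruvate with untreated cells was read first for the most changed genes, then for mitochondrial genes and their regulators, and then for other pathways. Only the pyruvate medium is described as made from DMEM without sodium pyruvate. Whether the basal DMEM held some is not given in the sources used here, so the untreated cells may have had pyruvate as well. No sample from the start of the 72 h was measured, so genes said to fall or rise were lower or higher than in untreated cells. No medium matched for sodium or osmolality was analysed here. Median signals lay between 30.3 and 33.0 on the 6 arrays. Pairs of arrays correlated at r = 0.985 to 0.991 across probe sets within a group and at 0.979 to 0.983 between groups (probe sets are not independent replicates), and no pair of arrays shared more than 0.951% of its values.

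Compared with untreated cells, genes of the contractile apparatus fell most with pyruvate, while the genes that rose most were of mixed function, with the chemokine gene Ccl7 first. Acta1, skeletal muscle actin, went from a signal of 982 ± 46.8 in untreated cells to 87.2 ± 8.30 in pyruvate (SD, n = 3 arrays each), a log2 change of -3.28 with a standard error of 0.07. Ccl7, whose product attracts monocytes, went from 48.5 ± 6.45 to 335 ± 14.6, a log2 change of 2.45 with a standard error of 0.10. Their adjusted p-values were 5.8e-10 and 3.7e-08, and for both genes all 3 pyruvate arrays lay outside the range of the untreated arrays. In total, 3678 probe sets were higher and 3572 lower with pyruvate, 32.2% of those tested, and 105 of them rose and 118 fell by at least 1 on the log2 scale. By gene, 2207 rose and 1546 fell, 63 and 67 of them by at least 1. In 48.6% of genes the arrays of the groups did not overlap, where chance gives 10%.

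The 12 genes that fell most were Tnnc2, Acta1, Actc1, Myog, Mybph, Rbm24, Mylpf, Tnni1, Tnnt3, Neb, Tnnc1 and Srl, with log2 changes from -3.30 for Tnnc2 to -2.15 for Srl. Most encode troponins, actins and other sarcomere or sarcoplasmic reticulum proteins, and Rbm24 is an RNA-binding protein of muscle. Mybph, Rbm24, Tnnt3, Neb and Srl had mean signals under the filter threshold in pyruvate cells, so their folds and ranks are limited by the floor of the arrays. The 12 that rose most were Ccl7, Anxa8, Hdc, Sgsm3, Ranbp3l, Srpx2, Ccl2, Hoatz, Ccn2, Ephx1, Igfbp7 and Selp, with log2 changes from 2.45 for Ccl7 to 1.72 for Selp. Ephx1, microsomal epoxide hydrolase, had the lowest adjusted p of these (7.2e-10), with mean signals of 621 in untreated and 2271 in pyruvate cells and a log2 change of 1.84 with a standard error of 0.04. Hdc, the enzyme that makes histamine, and Ranbp3l, Sgsm3 and Hoatz had mean signals under the filter threshold in untreated cells, so their folds rest on dim baselines.

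**Figure D1:**
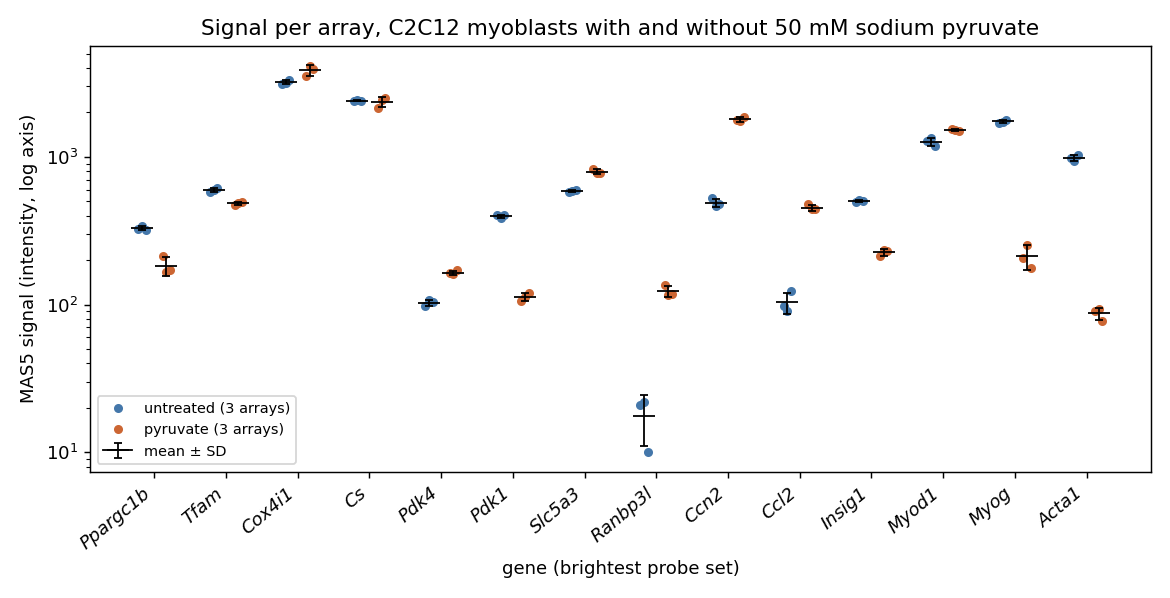
Signal per array for 14 genes (horizontal axis), each represented by its brightest probe set, on a logarithmic intensity axis; blue points are the 3 untreated arrays, orange points the 3 pyruvate arrays, and black marks their mean ± SD. Myog fell from 1738 to 212 and Ppargc1b from 328 to 183, Ccn2 rose from 490 to 1800, and the arrays for Cs overlapped.

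Muscle transcripts were lower across the list of myotube markers: of 29 measured members 26 fell and 2 rose, with a median log2 change of -1.80 (camera adjusted p = 1.2e-24, and adjusted p = 0.045 with an estimated correlation; 26 and 2 also when adjusted over the list alone). With quantile normalization and an estimated correlation together, neither this nor any other list passed (lowest adjusted p = 0.053). Myogenin (Myog), the transcription factor that starts terminal muscle differentiation, fell from 1738 ± 44.1 to 212 ± 40.1, a log2 change of -2.96. In untreated cells Myog and the myosin light chain Mylpf (1360) lay above the 95th percentile of signals (978 to 985), so differentiation genes were on in cells labelled undifferentiated. The members that rose, named after their values were seen, were Chrna1, a subunit of the muscle acetylcholine receptor (0.47), and Eno3, muscle enolase (0.26). The remaining member, Ckm, did not pass on its brightest probe set (-0.23, adjusted p = 0.17), while a dimmer Ckm probe set below the filter fell by 1.62 (adjusted p = 0.0034 without the filter).

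Regulators of myoblast identity moved both ways, with 3 of 11 higher, 6 lower and no call for the list (adjusted p = 0.16; median -0.24; the same counts adjusted over the list alone). Id1 and Id3, which hold back muscle differentiation by binding the partners of MyoD, rose by 1.23 and 1.00. Vgll2 and Mef2a, cofactor and factor of muscle gene expression, fell by 1.10 and 0.73. Myod1 itself rose by 0.26 (adjusted p = 0.0029), from 1268 ± 77.0 to 1525 ± 23.3.

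For the question in the title, the PGC-1 family was read gene by gene. Ppargc1a, which encodes PGC-1alpha, was near the floor of the arrays: all 5 of its probe sets lay below the signal filter, with mean signals no higher than 33.7 in either group. All 5 were lower in pyruvate cells in the mean, and 1 of them passed in the fit without the filter, at -0.67 (adjusted p = 0.015), from 16.9 to 4.70. Called probe sets below the filter leaned the same way in that fit, with 239 lower and 150 higher. The brightest went from 33.7 ± 5.70 to 27.1 ± 10.2, a log2 change of -0.23 with a 95% interval of -0.70 to 0.25 (adjusted p = 0.58), so a change in either direction was not resolved at this signal. Ppargc1b, encoding PGC-1beta, was well above the floor and fell from 328 ± 10.7 to 183 ± 26.0, a log2 change of -0.80 ± 0.09 (SE; adjusted p = 6.2e-05). Pprc1, another member of the family, was at 320 ± 26.7 and 308 ± 16.3 (-0.05, adjusted p = 0.62).

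Among the 25 measured regulators of mitochondrial biogenesis, 11 fell and 2 rose, the same counts when adjusted over the list alone. Besides Ppargc1b, Ssbp1, the mitochondrial single-strand DNA-binding protein, fell by 0.59 and the deacetylase Sirt1 by 0.47. Tfam, the factor that packages mitochondrial DNA and helps start its transcription, fell by 0.30 (adjusted p = 0.0012), from 599 ± 17.4 to 484 ± 10.7, and Gabpa, also called NRF-2 alpha, by 0.32 (adjusted p = 0.0034). The protease Lonp1 rose by 0.39, and Tefm, named after its value was seen, by 0.23. Nrf1 (0.04, adjusted p = 0.80) and Esrra (-0.01, adjusted p = 0.93) did not pass. The list median was only -0.04; camera placed the list below other genes (adjusted p = 0.046), but not with an estimated correlation (adjusted p = 0.45) nor after quantile normalization (adjusted p = 0.087).

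Nuclear genes for the respiratory chain were slightly higher in pyruvate cells as the authors scaled the arrays. For complex I, 12 of 32 genes rose and 1 fell, with a median of 0.14 (adjusted p = 0.0041, and adjusted p = 0.51 with an estimated correlation). For complexes II to IV with cytochrome c, 11 of 26 rose and 0 fell, with a median of 0.10 (adjusted p = 0.049, and adjusted p = 0.51 with an estimated correlation). For ATP synthase, 7 of 15 rose and 1 fell, with a median of 0.15 and no call (adjusted p = 0.077). Adjusted over the list alone, the counts were 14 higher and 2 lower, 11 and 0, and 9 and 1. Cox6c rose by 0.57, Cox6a1 by 0.40, Ndufc1 by 0.34, Atp5g1 by 0.46 and Cox4i1 by 0.27, from 3205 ± 88.8 to 3866 ± 308. Ndufs8 fell by 0.43 on its brightest probe set, but its arrays overlapped, and of its other 5 probe sets 1 was called lower, 1 higher and 3 did not pass. Cs, citrate synthase (-0.03, adjusted p = 0.72), and Cycs, cytochrome c (-0.02, adjusted p = 0.79), did not pass.

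These shifts depended on the scaling. Across the arrays, the brightest transcripts as a class were higher with pyruvate: among the 58 brightest probe sets 100% were higher, with a median of 0.52, while the 8655 probe sets between 7 and 9 had a median of 0.00. Spiked-in control transcripts were higher too, by a mean of 0.58 over 18 probe sets. After quantile normalization, which takes that trend out, complex I had 10 genes higher and 2 lower (median 0.10, adjusted p = 0.071), complexes II to IV had 4 higher and 5 lower (median -0.01, adjusted p = 0.58) and ATP synthase 2 higher and 4 lower (median -0.03, adjusted p = 0.20); Cycs then fell by 0.29 (adjusted p = 0.00018).

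**Figure D2:**
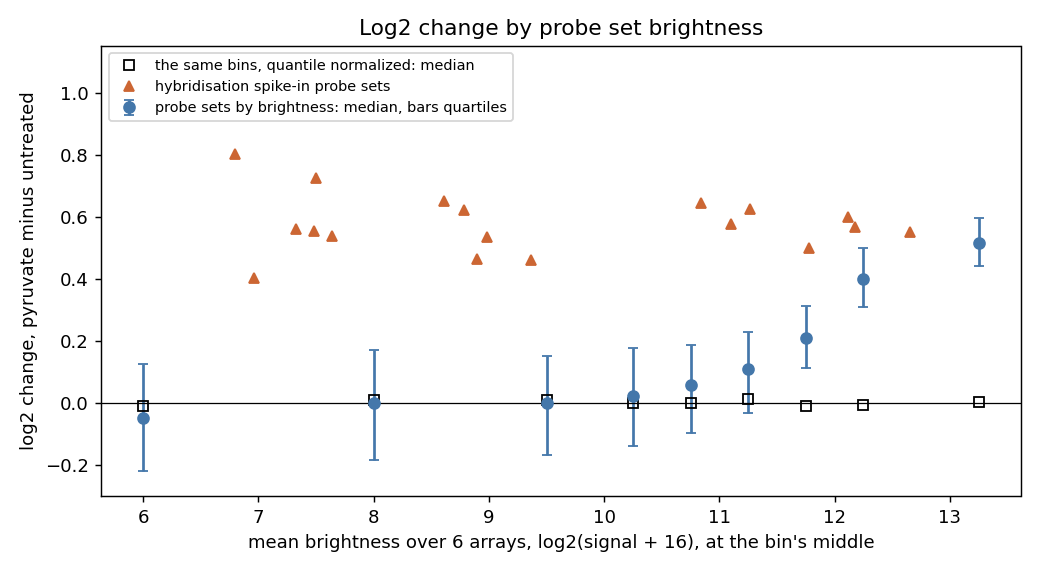
Log2 change with pyruvate (vertical axis) against mean brightness over the 6 arrays (horizontal axis, log2 of signal + 16); blue points are medians of probe sets in brightness bins with bars at their quartiles, open squares the same bins after quantile normalization, and orange triangles the 18 spiked-in control probe sets. The medians stay near 0 up to a brightness of 10 and reach 0.40 and 0.52 in the top bins, while the spiked-in controls lie between 0.40 and 0.80 at every brightness.

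Of 73 mitochondrial ribosomal proteins 20 rose and 4 fell (median 0.10, adjusted p = 0.0498, and adjusted p = 0.62 with an estimated correlation; 22 and 4 adjusted over the list alone), led by Mrps6 at 0.75. The list stayed past camera after quantile normalization (adjusted p = 0.037). For Mrpl13, which rose by 0.34, the other 2 probe sets were called lower. In fatty acid oxidation 9 of 21 rose and 1 fell (median 0.17, adjusted p = 0.038, and adjusted p = 0.34 with an estimated correlation; 11 and 1 over the list alone), including the carnitine palmitoyltransferases Cpt1c (1.39, from a dim 26.9) and Cpt1a (0.53), while Acat1 fell by 0.40. The TCA cycle (2 of 13 higher, 2 lower; adjusted p = 0.40), mitochondrial import and chaperones (4 of 27 higher, 3 lower; adjusted p = 0.97) and mitochondrial dynamics (4 of 13 higher, 3 lower; adjusted p = 0.97) gave no call. Adjusted over the list alone these were 2 and 2, 4 and 3, and 6 and 3. In mitochondrial dynamics the median was 0.16 while the mean was -0.01 and camera's direction was down. Bnip3, a mitophagy receptor, fell by 1.11, and whether camera's direction rests on it was not tested. None of the listed transcripts of the mitochondrial genome matched a probe set by symbol. A probe set annotated to ND5, chosen after its values were seen, was at 4063 ± 261 and 5213 ± 386 (0.36, adjusted p = 0.0018), among the bright probe sets, and at 0.00 after quantile normalization (adjusted p = 0.97).

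Genes that handle pyruvate and lactate rose and fell in similar number, 8 and 7 of 26 (also adjusted over the list alone; list adjusted p = 0.97, median 0.07, mean -0.03). Pdk1 and Pdk4 encode kinases that switch off pyruvate dehydrogenase. Pdk1 fell from 397 ± 9.31 to 112 ± 7.05, a log2 change of -1.69 (adjusted p = 5.8e-08), and Pdk4 rose from 103 ± 5.05 to 165 ± 5.08, a log2 change of 0.60 (adjusted p = 0.00026). The monocarboxylate transporters Slc16a1 and Slc16a3 fell by 0.29 and 0.69, alanine aminotransferase Gpt2 fell by 0.78, and malic enzyme Me1 rose by 0.61. Ldhb did not pass (0.17, adjusted p = 0.31), and Ldha was at 0.04 (adjusted p = 0.60) as scaled by the authors but at -0.28 after quantile normalization (adjusted p = 9.3e-05). In glycolysis 4 of 14 rose and 4 fell (adjusted p = 0.98; 5 and 4 over the list alone), with Pfkl falling by 0.64 and Pfkm rising by 0.51, both subunits of phosphofructokinase.

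Targets of hypoxia inducible factor were lower as a list: 9 of 21 fell and 3 rose (median -0.20, adjusted p = 0.0031, and adjusted p = 0.12 with an estimated correlation; 11 and 3 over the list alone). Besides Pdk1 and Bnip3, the prolyl hydroxylase Egln3 fell by 0.90, while Hmox1, heme oxygenase, rose by 1.16. Cholesterol synthesis and uptake fell more evenly, 11 of 19 lower and 0 higher (median -0.36, adjusted p = 4.1e-07, and adjusted p = 0.045 with an estimated correlation; 14 and 0 over the list alone). Insig1, which restrains sterol-regulated transcription and is itself induced by it, fell by 1.10, the cholesterol carrier Stard4 by 0.69, Idi1 by 0.57 and Cyp51 by 0.56. Fatty acid and triglyceride synthesis was mixed, with 6 of 21 higher and 10 lower (adjusted p = 0.21; the same counts over the list alone; median 0.01, mean -0.07), Acsl3 and Elovl6 falling by 0.81 and 0.78.

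Genes induced by hypertonic medium were higher: 13 of 17 rose and 1 fell, with a median of 0.43 (adjusted p = 9.1e-07, and adjusted p = 0.045 with an estimated correlation; 14 and 1 over the list alone). Ranbp3l rose by 2.07, the matrix proteoglycan Bgn by 0.96, the chaperone Hspa1b by 0.81 and the sodium pump subunit Atp1b1 by 0.71. Bgn is also on the list of extracellular matrix genes and Hspa1b on that of heat shock proteins, so these lists are not independent. The transporters of the osmolytes inositol and taurine, Slc5a3 and Slc6a6, rose by 0.43 and 0.32, from 586 ± 6.82 to 796 ± 28.4 and from 1632 ± 82.2 to 2042 ± 59.4, though the other 3 Slc6a6 probe sets did not pass. Car2, the member that fell and named after its value was seen, did so by 0.32.

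Targets of TGF-beta, BMP and YAP were higher as well, 15 of 22 with 1 lower (median 0.51, adjusted p = 9.1e-07, and adjusted p = 0.045 with an estimated correlation; 16 and 1 over the list alone). Ccn2, connective tissue growth factor, rose from 490 ± 32.6 to 1800 ± 63.9 (1.85), Tagln, a smooth muscle actin-binding protein, by 1.41, Id1 by 1.23 and Ccn1 by 1.06. Ccn3, named after its value was seen, fell by 0.71. Extracellular matrix genes had 13 of 25 higher and 1 lower (median 0.15, adjusted p = 0.0014, and adjusted p = 0.30 with an estimated correlation; 14 and 3 over the list alone), with Lox, which crosslinks collagen, rising by 1.00 and Col5a3 falling by 0.81. Matrix proteases and their inhibitors gave no call (5 of 12 higher, 1 lower; adjusted p = 0.16; the same counts over the list alone), and among them the inhibitors Timp3 and Timp1 rose by 0.77 and 0.66.

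**Figure D3:**
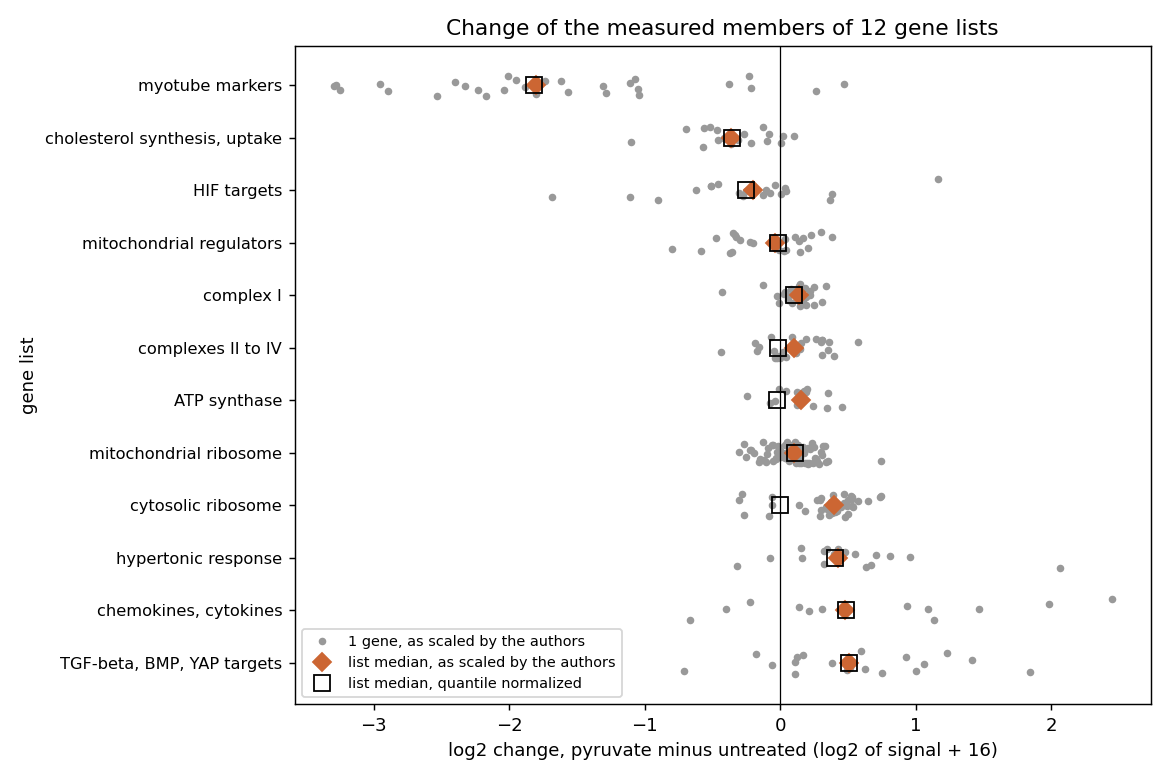
Log2 change with pyruvate (horizontal axis) of every measured member of 12 gene lists (vertical axis); grey points are genes, orange diamonds the list medians as the authors scaled the arrays, and open squares the medians after quantile normalization. The myotube markers have a median of -1.80 and the hypertonic list one of 0.43 with little change after quantile normalization, while the cytosolic ribosome moves from 0.40 to 0.00.

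Inflammatory and stress genes followed. Chemokines, cytokines and NF-kappaB targets had 8 of 13 higher and 2 lower (median 0.48, adjusted p = 0.0014, and adjusted p = 0.12 with an estimated correlation; 9 and 2 over the list alone). Next to Ccl7, Ccl2 rose from 104 ± 17.0 to 454 ± 21.4 (1.98), Cxcl5 by 1.47 and Ccl8 by 1.14. Vcam1 and Il33, named after their values were seen, fell by 0.67 and 0.40. Antioxidant genes of the NRF2 list had 16 of 25 higher and 3 lower (median 0.25, adjusted p = 0.0013, and adjusted p = 0.24 with an estimated correlation; 17 and 4 over the list alone). Hmox1, Nqo1 and Gsta4 rose by 1.16, 0.98 and 0.84, whereas the metallothionein Mt2 fell by 0.75. After quantile normalization 12 members were higher and 5 lower, with a median of 0.16 (adjusted p = 0.039). Heat shock proteins had 8 of 15 higher and 1 lower (median 0.23, adjusted p = 0.0014, and adjusted p = 0.12 with an estimated correlation; 10 and 1 over the list alone), led by Cryab at 0.86, but the list was not called after quantile normalization (adjusted p = 0.098). The lists of ATF4 targets (11 of 32 higher, 1 lower; adjusted p = 0.10), ER chaperones (6 of 20 higher, 3 lower; adjusted p = 0.97), p53 targets (9 of 17 higher, 3 lower; adjusted p = 0.29) and interferon response (2 of 12 higher, 1 lower; adjusted p = 0.85) were not called. Over the list alone the counts were 13 and 3, 7 and 3, 9 and 4, and 2 and 1. Cdkn1a, the p21 cell cycle inhibitor, was at 1480 ± 121 and 1498 ± 200.4 (0.01, adjusted p = 0.93).

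Cytosolic ribosomal proteins rose in 35 of 42 measured genes and fell in 3 (median 0.40, adjusted p = 9.4e-11, and adjusted p = 0.37 with an estimated correlation; the same counts over the list alone). Rps15 and Rpl41 rose by 0.74 and Rps2 by 0.65, though of the other 3 Rpl41 probe sets 1 was called lower and 1 did not pass. The members that fell, Rpl12, Rpl14 and Rps25, named after their values were seen, were the dim ones, with signals of 202, 210.2 and 347 in untreated cells. These genes are among the brightest on the array, where the spiked-in controls and other bright transcripts were also higher, and after quantile normalization 4 were higher and 11 lower (median 0.00, adjusted p = 0.22). Cyclic loess kept the list called at a median of 0.22 (adjusted p = 7.4e-08), while it also left the 58 brightest probe sets at a median of 0.31. Lysosome and autophagy genes had 11 of 27 higher and 0 lower (median 0.12, adjusted p = 0.0056, and adjusted p = 0.12 with an estimated correlation; 11 and 0 over the list alone), led by Gabarapl1 and Npc2 at 0.50, and were not called after quantile normalization (adjusted p = 0.19).

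Proliferation genes shifted little. Of 27 genes of G2 and mitosis 8 fell and 2 rose (median -0.09, adjusted p = 0.049, and adjusted p = 0.51 with an estimated correlation; 8 and 2 over the list alone), with the checkpoint kinase Bub1 falling by 0.54 and Mki67 by 0.27. After quantile normalization 0 were higher and 10 lower (median -0.11, adjusted p = 0.025). In S phase and replication 8 of 24 fell and 6 rose (adjusted p = 0.40; the same over the list alone), Ccne2 falling by 0.71 and Tk1 rising by 0.59. Ribosome biogenesis and MYC targets (7 of 28 higher, 2 lower; adjusted p = 0.20), the proteasome (8 of 31 higher, 2 lower; adjusted p = 0.58), amino acid and glucose transporters (4 of 11 higher, 2 lower; adjusted p = 0.80) and histone deacetylases, sirtuins and acetyltransferases (5 of 22 higher, 4 lower; adjusted p = 0.97) were not called. Over the list alone the counts were 9 and 2, 9 and 5, 5 and 4, and 5 and 4.

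Markers of other cell types were mostly below the signal filter. Adipocyte markers had 3 of 13 measured, of which Lpl rose by 1.08 and Cebpa by 0.84, both from signals under 150, with Pparg at 0.24 (adjusted p = 0.29); the list was called at an adjusted p of 0.041, but at an adjusted p of 0.27 with an estimated correlation (2 and 0 over the list alone). Osteoblast and chondrocyte markers had 4 measured and 0 called (list adjusted p = 0.88; 0 adjusted over the list alone), with Phex at 0.25 (adjusted p = 0.24) and Sox9 at 0.12 (adjusted p = 0.30). Macrophage and blood cell markers had 4 measured and 1 higher, Cd14 at 0.95 (list adjusted p = 0.42; 1 and 0 over the list alone). Epithelial, endothelial and neural markers had 1 of 9 higher, Krt14 at 1.12, and 4 lower, with Map2 falling by 0.76 (list adjusted p = 0.22; 1 and 4 over the list alone).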

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

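The values below concern control probe sets, probe sets under the signal filter and the brightest transcripts, and every test in this part except the brightness-matched comparisons of cytosolic ribosomal and of pooled respiratory chain genes was chosen after the result was seen.

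The spiked-in hybridisation controls, bacterial and phage transcripts normally added to each sample in a fixed amount, had a mean log2 difference of 0.58 in the pyruvate arrays (lowest 0.40, highest 0.80 over 18 probe sets). Control probe sets for 18S ribosomal RNA were higher by 0.86 (3 prime), 0.73 (5 prime) and 0.52 (middle), with exact permutation p-values of 0.1, 0.1 and 0.2, where 0.1 is the smallest that 3 against 3 arrays allow. Actin controls were higher by 0.56 at both the 3 prime and the 5 prime end, and Gapdh controls by 0.54 and 0.53. Among the 22518 probe sets under the filter, 150 were higher and 239 lower in the fit without it, among them, chosen after their values were seen, Ckm (-1.62), Trim63 (-1.32) and Unc45b (-1.19) on dim muscle probe sets.

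A pattern that goes with the spiked-in, actin and Gapdh controls is that the brightest transcripts were higher with pyruvate. A candidate explanation is that less labelled RNA reached the pyruvate arrays: scaling then raises the spiked-in controls, and raises bright probe sets near saturation by at most as much. The median change of the 58 brightest probe sets was 0.52, not above the highest spiked-in control (0.80). The 3 pyruvate arrays had one order for the mean of the controls (0.36, 0.51 and 0.86) and for the median of these probe sets (0.41, 0.47 and 0.65). Both results go with this explanation but weigh little. The highest of 18 controls is a lenient bound, and 3 arrays can share an order by chance. On pyruvate array 1 these probe sets (0.41) lay above the mean of the controls (0.36), which is more than the explanation allows if that mean is its bound. The 18S controls are neither spiked in nor bright, with mean signals of 48.4 to 71.3 in untreated cells. The explanation does not account for their rise. Against probe sets of like brightness, cytosolic ribosomal genes differed by only 0.011 (random lists -0.05 to 0.05) and complexes II to IV with ATP synthase by -0.023 (-0.06 to 0.07), so neither was seen to move beyond its brightness class. The 0.22 of ribosomal genes under cyclic loess stands beside 0.31 for the 58 brightest probe sets. Probe sets with several or no symbols stayed among those compared, and 33 of 76 listed ribosomal genes had no probe set of 1 symbol. The ribosomal genes may thus have been compared partly with other ribosomal probe sets, which would draw their difference toward 0. The pooled respiratory chain and ATP synthase genes stood 0.057 higher (-0.05 to 0.05), complex I 0.10 (-0.09 to 0.08) and mitochondrial ribosomal proteins 0.11 (-0.07 to 0.07, 53 of 73 members above). Members of the random lists were drawn independently of each other, so these ranges treat genes as independent. The estimated correlation was 0.29 within complex I and 0.14 within mitochondrial ribosomal proteins, so the ranges may be too narrow. A small rise of complex I and of mitochondrial ribosomal genes with pyruvate therefore stays open as a hypothesis, as does a true rise of abundant transcripts in general, since no array here separates labelling from treatment.

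The real split of the 6 arrays gave 7250 changed probe sets and the highest of the others 0, so 1 of 10 splits gave as many. Splits of 3 against 3 are too few for a share under 0.05.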

How the results depend on the processing

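The myotube, hypertonic, cholesterol and TGF-beta lists kept their direction and their call under every alternative taken alone. With quantile normalization and an estimated correlation together their adjusted p-values were 0.053, and 0 lists passed. Ppargc1b stayed between -0.67 and -0.90. The number of changed probe sets, 7250, lay between 5376 and 7500 under all alternatives but the minimum log2 change of 1, which by its construction left 223 (105 higher, 118 lower). With the replicate number as a block it was 6917. Residuals of samples with the same number correlated at -0.009 to 0.021, under 0.1, so no shared effect of the number was seen. Whether samples of the same number were handled together is not settled by this. Of 201 named genes 10 reversed and 21 lost their call under some alternative, and with the stricter signal filter only 180 of them could be compared. Single genes, Ppargc1b among them, were not compared under cyclic loess, the mean over a gene's probe sets or the minimum log2 change. The median shift between the groups' arrays was -0.05 and the difference of trimmed means 0, by the authors' scaling. Of 39 lists 18 passed camera, 4 with an estimated correlation, 28 by fry and 38 by fry in either direction. With an estimated correlation the lowest camera adjusted p of any list was 0.045. It was no lower for the hypertonic list, whose estimate of -0.04 lay below the preset 0.01. A call lost in that setting is thus not by itself a sign of correlated members. Signal over background limits dim genes such as Ppargc1a.

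Values below are median log2 changes of lists, or log2 changes of genes, with the adjusted p in brackets; the cause was not tested. With quantile normalization: ATP synthase -0.025 (0.20), complexes II to IV -0.014 (0.58), complex I 0.10 (0.071), PGC-1 family and regulators -0.019 (0.087), cytosolic ribosome 0.0020 (0.22). Reversed there were also ER chaperones -0.0026, glycolysis -0.062, mitochondrial dynamics -0.057, proteasome -0.037, Atp5b -0.056, Atp5g3 -0.068, Cdkn1a -0.034, Hspb1 -0.016, Hspd1 -0.022, Ldha -0.28 and Mdh2 -0.0090. With cyclic loess, chosen after seeing the data: complex I 0.059 (0.41), complexes II to IV 0.015 (0.82), PGC-1 family and regulators -0.021 (0.077), mitochondrial ribosome 0.091 (0.073), cytosolic ribosome 0.22 (still called, 7.4e-08), ER chaperones and unfolded protein response -0.00659, mitochondrial protein import, chaperones and proteases -0.00488 and proteasome -0.066. With an estimated correlation the medians stay and the call is lost: complex I 0.14 (0.51), complexes II to IV 0.10 (0.51), PGC-1 family and regulators -0.039 (0.45), cytosolic ribosome 0.40 (0.37), mitochondrial ribosome 0.099 (0.62) and HIF targets -0.20 (0.12). With the mean over a gene's probe sets: complexes II to IV 0.053 (0.23), PGC-1 family and regulators -0.088 (0.11), mitochondrial ribosome 0.078 (0.11), ER chaperones -0.046, fatty acid and triglyceride synthesis -0.046, glycolysis -0.013, mitochondrial dynamics -0.073, mitochondrial import -0.00603 and proteasome -0.012.

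Without the variance trend: complexes II to IV 0.10 (0.13), PGC-1 family and regulators -0.039 (0.088) and mitochondrial ribosome 0.099 (0.090). With median centring: complexes II to IV 0.10 (0.066) and mitochondrial ribosome 0.099 (0.054). The mitochondrial ribosome was also not called at 0.099 with the stricter signal filter (0.10) and with the replicate block (0.053). ATP synthase was called with array weights at 0.16 (0.049), and at 0.15 without the filter (0.025) and by fry in either direction (0.0021). Fry in either direction passed 38 of 39 lists, so that call says little about ATP synthase. Other lists lost their call too. Fatty acid oxidation did with cyclic loess (0.074), the stricter filter (0.11), the mean over probe sets (0.11), no variance trend (0.051) and in 4 of 6 leave-outs. G2 and mitosis did with the stricter filter (0.060), no variance trend (0.081), the block (0.053), fry (0.075) and in 3 of 6 leave-outs. Adipocyte markers did with the stricter filter (0.15), no filter (0.19) and in 2 of 6 leave-outs. Lysosome genes did with cyclic loess (0.060) and quantile normalization (0.19), and heat shock proteins with the latter (0.098). Without the filter, transporters were at -0.067 and glycolysis at -0.013. With the stricter filter, fatty acid and triglyceride synthesis was at -0.18. Leaving out 1 array at a time gave ATP synthase 0.13 to 0.19 (called in 4 of 6, adjusted p = 0.010 to 0.048), complexes II to IV 0.062 to 0.13 (call lost in 4 of 6, 0.070 to 0.16), PGC-1 family and regulators -0.076 to -0.0043 (lost in 3 of 6, 0.053 to 0.093) and mitochondrial ribosome 0.082 to 0.12 (lost in 4 of 6, 0.080 to 0.15). Lists and genes that reversed there were ER chaperones -0.012 to 0.053, S phase -0.045 to 0.0065, fatty acid and triglyceride synthesis -0.062 to 0.0096, mitochondrial import -0.042 to 0.034, Cdkn1a -0.076 to 0.12, Cs -0.073 to 0.030, Cycs -0.065 to 0.030 and Esrra -0.034 to 0.017.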

Other observations

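Further genes stood out that the rule for named genes did not take; those in this paragraph were chosen after their values were seen. They were picked singly, and no list of Notch genes was tested. The Notch ligand Dll1 fell from 221 ± 12.1 to 71.8 ± 7.10 (SD, n = 3 arrays each; log2 change -1.43), the transcription factors Heyl, Hey1 and Hes1, which Notch induces, fell by 1.21, 0.55 and 0.40, and Dtx4, a ubiquitin ligase, fell by 1.36. Among receptors Notch3 fell by 0.67 and Notch1 by 0.36 while Notch2 rose by 0.22, and the ligand Jag1 did not pass (-0.28, limma adjusted p = 0.21). The axon guidance genes Sema3c and Sema3e fell by 1.39 and 1.31, the transcription factor Sox11 by 1.41, and the imprinted genes Mest and Igf2 by 1.73 and 1.00. E2f2, a cell cycle transcription factor, fell by 1.51. Among genes that rose, Sod3, extracellular superoxide dismutase, changed by 1.60, the lipid droplet protein Plin4 by 1.62, the peptide hormone gene Cck by 1.56, the small heat shock protein Hspb6 by 1.30 and the macrophage growth factor Csf1 by 1.09. All changes given as falls or rises had limma adjusted p-values under 0.05.

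The tests in the following paragraphs were chosen after the results were seen. Myotube genes were lower with pyruvate, with a list median of -1.80. The brightness trend between the arrays argues little for this, since the median was -1.82 after quantile normalization. The list then passed camera at the preset correlation but not with an estimated one (adjusted p = 0.053). More cycling cells in place of differentiating ones would raise genes of G2 and mitosis, whose median was -0.088 (2 higher, 8 lower), and -0.11 after quantile normalization (0 higher, 10 lower; camera adjusted p = 0.025). Those values go against it. At the preset correlation camera called the list lower in both scalings, though some alternatives lost the call. The test set for it, camera with an estimated correlation, was not passed in either scaling (adjusted p = 0.51 and 0.45). That test could not decide on so small a shift. As scaled by the authors, it gave even the myotube list an adjusted p of only 0.045. The explanation by more cycling cells therefore stays open. Higher TGF-beta and BMP signalling, which may act through Id1 and Id3, is a hypothesis: targets of TGF-beta, BMP and YAP had a median of 0.51, but Id1 and Id3 are themselves on that list, and a single time point on the same arrays does not order the events. Culture density at harvest was not recorded in the labels and stays open, as does whether pyruvate lowered these transcripts or kept them from rising as in untreated cells.

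Genes of the hypertonic response were higher, with a list median of 0.43. The brightness trend argues little for this too, since the median was 0.40 after quantile normalization. The list then passed camera at the preset correlation but not with an estimated one (adjusted p = 0.053). As scaled by the authors, its estimated correlation was -0.04, below the preset 0.01. Its camera adjusted p still went from 9.1e-07 to 0.045 with the estimate, so correlated members do not account for that weaker call. A candidate explanation is the sodium and the osmolality of the medium, since 50 mM sodium pyruvate adds both. With the sodium and the pyruvate given together in every treated sample, the median of 0.43 cannot be told apart from an effect of pyruvate itself. The same doubt covers the other gene groups of the comparison, whose link to osmolality was not tested.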
